A study of Mus musculus with 16 samples.

How the data were processed

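RNA from 3T3-L1 cells, a mouse fibroblast line committed to the adipocyte lineage, was measured on 2-colour long-probe arrays. Per the labels, total RNA was purified with RNeasy kits and reverse transcribed with an amino allyl nucleotide, to which the dye was coupled, with the sample in Cy5 and a pool of the samples in Cy3. The labels give 4 groups, which are dex and its DMSO vehicle at 2 h and at 36 h, with 4 biological replicates each and 16 arrays in all. All arrays have the same dye orientation, so a dye effect on a probe adds the same amount to every array and drops out of the differences between groups.

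The deposited values are log ratios of sample over pool, 1 per probe and array, and were used as log2 values. The log base, the background correction and the normalization within arrays are not given in the sources used here. Per the labels' dyes and the design text, the direction is Cy5 over Cy3, and the authors fitted linear models in limma, whose ratios are on the log2 scale. This reading was checked on the values, since the arithmetic mean of sample over pool should be near 1. For the 39 most variable probes the median over probes of that mean was 1.00 with the values read as log2 in this direction, 2.76 with the sign turned, 2.98 with base 10 and 1.13 with the natural log. For the 384 most variable probes it was 0.976 with log2 and 1.01 with the natural log, and for the 3834 most variable 1.01 and 1.04. These values count against the turned sign and base 10 but do not settle log2 against the natural log, and with the latter each stated log2 change would be larger by a constant factor. Base 2 was taken because limma's ratios have it. The ratios were not centred per probe, as probe means over the 16 arrays had an SD of 0.116.

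The array medians were 0.0083, -0.0033, -0.0020 and -0.0071 in DMSO 2 h replicates 1 to 4, and -0.0032, 0.0017, -0.0036 and -0.0023 in dex 2 h. In DMSO 36 h they were -0.0030, -0.0022, -9.42e-04 and 0.0014, and in dex 36 h -0.0047, 6.09e-04, -0.011 and -0.0034. No further normalization was applied. Of the values, 131 were missing, on 3 arrays. Every probe had values on at least 3 of 4 arrays of each group, the minimum set, so none of the 38467 probes was removed. Among 16 arrays, those of dex 36 h replicates 1 and 3 correlated negatively with DMSO 36 h replicate 2 across probes (r = -0.34 for both), as opposed conditions measured against a pool of both can. The labels state the dyes, so the direction was kept. Within groups the correlation across probes was 0.527 to 0.684 for DMSO 36 h, 0.16 to 0.794 for dex 36 h, 0.12 to 0.383 for dex 2 h and -0.256 to 0.349 for DMSO 2 h. In the last group replicate 4 correlated negatively with replicates 1 and 2, and its mean r with the group was -0.104. No scanner intensities were analysed here, so signal over background is unknown. The number of arrays and their noise, which was greater at 2 h, limit the precision.

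The platform's annotation named a single gene for 29456 probes, several for 760 and none for 8251. Symbols were looked up by Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, which was used for names alone. It held 28735 of the probes with 1 gene, and 721 kept the platform's symbol. The named probes covered 19640 genes, of which 6325 had several probes. No genome position is given, because the sources used here name no build for the probes.

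Per probe, limma 3.58.1 in R 4.3.3 fitted the means of the 4 groups over all 16 arrays with lmFit and eBayes, without covariates. The residual degrees of freedom were 12 and the prior ones 3.19. The contrasts were dex against DMSO at 2 h, dex against DMSO at 36 h, the difference between these effects, and DMSO at 36 h against 2 h. P values were adjusted by the Benjamini-Hochberg method over the 38467 probes of each contrast, and a gene passed where at least 1 probe naming only that gene had an adjusted p under 0.05. The design text counted a gene where the log-odds of 1 probe exceeded 50:50, which was an alternative here. A value quoted for a gene is that of 1 probe, the one with the smallest p in the moderated F test of both dex contrasts. Errors of differences are standard errors (SE) of the fitted contrast with n = 4 arrays per group. They rest on 1 variance per probe over all 16 arrays, so a probe without missing values has the same SE at 2 and 36 h. As the 2-hour arrays were noisier, the SE tends to understate the spread at 2 h and to overstate that at 36 h.

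Before the data were examined, the design, the alternatives, the gene lists and the rule for genes to name were fixed. The rule took the 10 largest rises and falls at each time among genes that passed and whose 4 dex arrays lay to one side of the 4 DMSO arrays. From each list it took up to 4 genes that passed and up to 2 that did not, from the difference between times the 8 largest each way, from vehicle over time the 6 largest each way, and 14 genes in every case (Nr3c1, Fkbp5, Tsc22d3, Per1, Cebpa, Cebpb, Cebpd, Pparg, Dlk1, Fabp4, Adipoq, Hsd11b1, Il6 and Ccl2). It gave 231 genes, of which 98 are described. These 98 were picked from the 231 after their values had been seen, and genes outside the rule are said to be so where they appear.

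There were 25 lists with 593 genes, 557 of them measured and 47 in more than 1 list. They covered glucocorticoid receptor target genes, receptor and steroid metabolism, adipogenic transcription factors, mature adipocyte genes, preadipocyte markers and inhibitors of adipogenesis, osteoblast genes, cartilage genes, skeletal muscle genes, contractile and actin cytoskeleton genes, inflammatory and NF-kappaB target genes, interferon response genes, extracellular matrix genes, cell cycle genes, cyclin-dependent kinase inhibitors and quiescence genes, circadian clock genes, immediate early genes, insulin and IGF signalling genes, cholesterol synthesis genes, metallothionein and antioxidant genes, Wnt pathway genes, TGF-beta and BMP pathway genes, macrophage, endothelial and epithelial markers, and housekeeping genes. The camera test compared each list with the other genes on the mean of each gene's probes, at a preset correlation of 0.01 and again with an estimated correlation, with p values adjusted over the 25 lists and both dex contrasts together. For the other contrasts they were adjusted in the same way over the lists.

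The procedure was tested on simulated data, 10 runs per comparison of 38467 probes with the measured noise of each probe and array and 200 probes changed by a known amount. At 2 h, 38.5%, 79.0% and 98.2% of changes of 0.5, 1 and 2 (log2) were recovered, and 54.4 unchanged probes passed per run (27.5% of calls). At 36 h the recovered shares were 33.7%, 81.9% and 97.3%, with 0 unchanged probes per run. For the difference between times they were 11.2%, 58.5% and 93.2%, with 6.4 unchanged probes per run (5.58% of calls), and for vehicle over time 35.5%, 83.6% and 98.2%, with 14.3 (9.00%). The list test was simulated once, for dex at 36 h, on 19640 genes with lists of 30 genes. The 1 list moved by 0.5 (log2) passed, and 0 of 24 unmoved lists did. In all these simulations the noise was independent between probes. They could not show the effect of correlation between genes or of deviations shared by arrays, nor the recovery of lists with smaller shifts.

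The alternatives were centring each array, quantile normalization, centring with scaling, the log-odds threshold, a minimum change of 1 (log2), no or a stricter filter on missing values, a fit of only the groups compared, the replicate number as a block, array weights, a robust variance prior, the mean over a gene's probes, and leaving out each array in turn. A fit without the 3 most variable 2-hour arrays and one of probes with a listed gene only were added after seeing the data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and tables were handled in R with version 1.17.8 of its data.table package.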

Results

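Gene expression was measured in 3T3-L1 cells, a mouse preadipocyte line that can be induced to become adipocytes. The cells received dexamethasone (dex), a synthetic glucocorticoid, or its solvent DMSO for 2 or 36 h, and total RNA of 4 biological replicates per group was hybridised in Cy5 against a pool of the samples in Cy3. The 16 arrays held 38467 probes, of which 29456 named 1 of 19640 genes. The array medians lay between -0.011 and 0.0083 on the log scale of the ratios, whose base is not given in the sources used here and was taken as 2. The number of arrays and their noise limit the precision, and signal over background is not known.

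The first comparison asked which genes responded to 2 h of dex. Glul, encoding glutamine synthetase, rose 8.51-fold (log2 change 3.09 ± 0.21, SE, n = 4 per group, limma adjusted p = 4.51e-07). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose 6.77-fold, and Zbtb16, a zinc finger transcription factor, 6.38-fold. Dusp1, a phosphatase of MAP kinases, rose 5.66-fold and Fkbp5, a co-chaperone of the glucocorticoid receptor, 5.15-fold. The chemokine genes Cxcl5, Ccl7 and Ccl2 were 5.48-fold, 3.66-fold and 3.57-fold lower. Their log2 changes were -2.45 ± 0.23, -1.87 ± 0.16 and -1.83 ± 0.14, with limma adjusted p = 1.25e-05, 4.88e-06 and 1.31e-06. For each of these genes the 4 dex arrays lay on one side of the 4 DMSO arrays.

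Among 19640 genes, 625 changed at 2 h, 387 upward and 238 downward, and 136 of them by at least 1 on the log2 scale (107 up, 29 down). The 10 largest rises with separated arrays also held Slc45a3 (3.03 ± 0.21), the small GTPase gene Rhob (2.32 ± 0.09) and Tcim (2.21 ± 0.16). They further held the ERBB receptor feedback inhibitor gene Errfi1 (2.19 ± 0.22) and the protease gene Adamts15 (2.16 ± 0.21). The other probe of Errfi1 gave -0.01, and 1 of the 4 probes of Tsc22d3 gave -0.07. The 10 largest falls included Angptl4 (-1.72 ± 0.15), an inhibitor of lipoprotein lipase, the kinase gene Plk2 (-1.68 ± 0.09) and the hyaluronan synthase gene Has2 (-1.66 ± 0.14). Next came Cxxc5 (-1.55 ± 0.12), Socs5 (-1.50 ± 0.13), the iron exporter gene Slc40a1 (-1.41 ± 0.07) and Enc1 (-1.38 ± 0.12). The other probe of Socs5 gave -0.15. The 4 dex arrays were apart from the 4 DMSO arrays for 2253 probes, or 5.86%, where chance gives 2.86%.

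**Figure D1:**
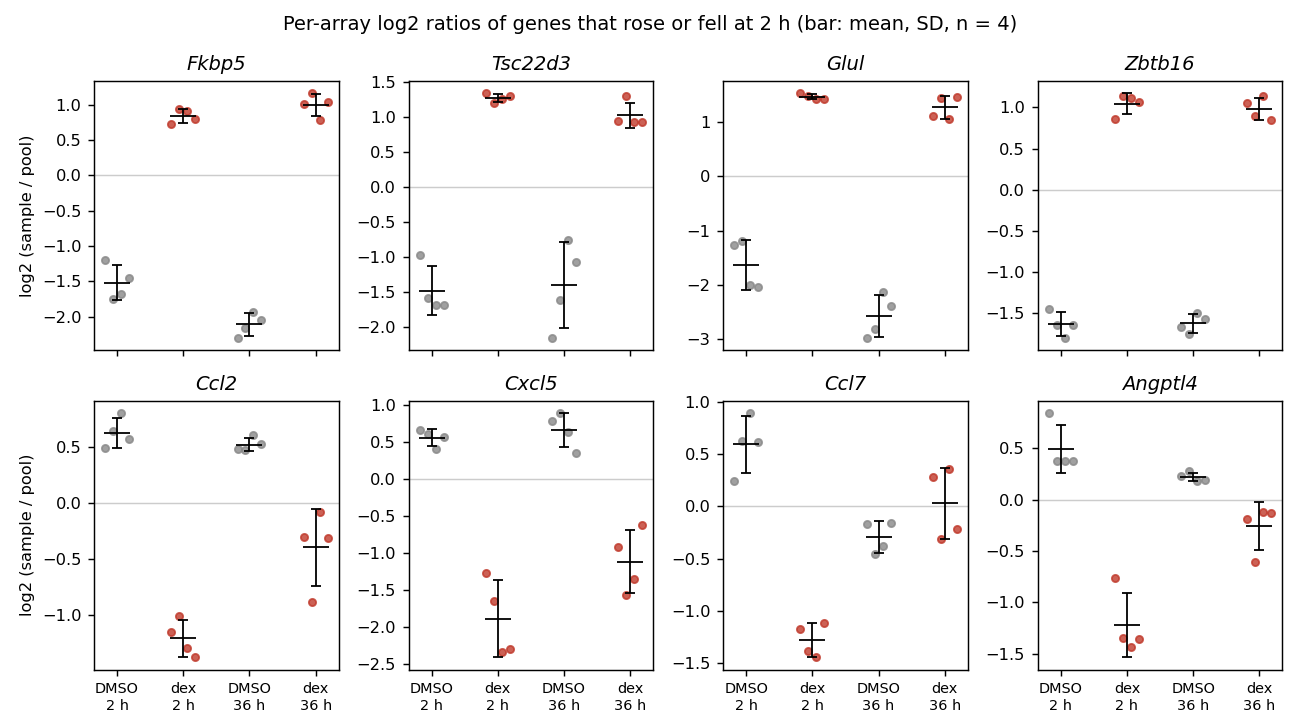
Log2 ratio of sample over pool (vertical axis) on each of the 16 arrays for 8 genes, 1 probe per gene, in the 4 groups, with bars for mean and SD (n = 4). At 2 h the 4 dex arrays lay above the 4 DMSO arrays for Fkbp5, Tsc22d3, Glul and Zbtb16 and below them for Ccl2, Cxcl5, Ccl7 and Angptl4.

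Of 39 measured glucocorticoid receptor target genes, 25 rose and 1 fell at 2 h (31 and 2 adjusted over the list alone). The camera adjusted p was 3.35e-43 (adjusted p = 3.10e-04 with an estimated correlation). The gene that fell was Angptl4, itself known as a target in adipose tissue. Of the 12 receptor and steroid metabolism genes 3 rose and 0 fell (4 and 1 over the list alone, camera adjusted p = 0.0164, adjusted p = 0.235 with an estimated correlation). The list's median of -0.0068 lay below 0 while its mean of 0.26 and its test were upward. The receptor gene Nr3c1 had a value of -0.48 ± 0.12 and did not pass (adjusted p = 0.0568). Among 29 adipogenic transcription factors 5 rose and 1 fell (6 and 1 over the list alone, camera adjusted p = 0.00498, adjusted p = 0.319 with an estimated correlation). Cebpb (1.02 ± 0.10) and Cebpd (0.93 ± 0.13), which act early in adipocyte differentiation, rose. So did Klf9 (1.07 ± 0.12) and, by 1 of 3 probes, Klf5 (1.32 ± 0.18). Cebpa, which acts later, fell by 0.55 ± 0.13. Pparg, the main regulator of adipocyte differentiation, had a value of -0.22 ± 0.15 (adjusted p = 0.652).

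The 34 preadipocyte markers and inhibitors of adipogenesis had 3 rises and 10 falls (4 and 11 over the list alone). The list moved down (camera adjusted p = 1.39e-04, adjusted p = 0.066 with an estimated correlation). Gata2 (-0.91 ± 0.16) and Klf3 (-0.80 ± 0.09), both repressors of adipogenesis, fell, while Dlk1, the preadipocyte marker Pref-1, had a value of 0.01 ± 0.17. Of 39 inflammatory and NF-kappaB target genes 3 rose and 10 fell (6 and 14 over the list alone, camera adjusted p = 7.51e-04, adjusted p = 0.104 with an estimated correlation). Il6 fell by 0.59 ± 0.12, whereas Lcn2, encoding lipocalin 2, rose by 1.57 ± 0.26. The 29 Wnt pathway genes had 2 rises and 5 falls (4 and 6 over the list alone, camera adjusted p = 0.0124, adjusted p = 0.103 with an estimated correlation). Of the 19 contractile and actin cytoskeleton genes 0 passed in limma, and 7 had an unadjusted p under 0.05, all lower with dex. As a list they were lower (camera adjusted p = 0.0107, adjusted p = 0.103 with an estimated correlation).

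The other lists did not pass the camera test at 2 h. Of 32 mature adipocyte genes 3 rose and 1 fell (4 and 1 over the list alone, adjusted p = 0.104). Fabp4, a fatty acid carrier, rose by 1.60 ± 0.31, Lpin1 by 1.03 ± 0.15 on all 3 probes and Plin4 by 0.57 ± 0.09. Lpl, encoding lipoprotein lipase, fell by 0.47 ± 0.08 on 1 of 2 probes. Of 36 immediate early genes 9 rose and 6 fell (11 and 9 over the list alone, adjusted p = 0.19). Of 20 cyclin-dependent kinase inhibitors and quiescence genes 3 rose and 4 fell (5 and 6, adjusted p = 0.529). Gadd45g (1.75 ± 0.12) and Cdkn1a (0.85 ± 0.08) were among the rises. In the circadian clock list of 19 genes, 3 rose and 1 fell (3 and 2, adjusted p = 0.841). Per1 rose by 1.06 ± 0.16 and Per2 by 0.79 ± 0.15. For 26 insulin and IGF signalling genes there were 4 rises and 2 falls (4 and 3, adjusted p = 0.6). Foxo3 rose by 1.44 ± 0.10 on 3 of 4 probes, and the receptor substrate gene Irs1 fell by 0.82 ± 0.12. The 21 metallothionein and antioxidant genes had 2 rises, of Mt1 (1.37 ± 0.11) and Mt2 (1.74 ± 0.11), and 1 fall (2 and 3, adjusted p = 0.9999). Of 49 extracellular matrix genes 4 rose and 2 fell (9 and 5, adjusted p = 0.223), with Adamts1 at 1.42 ± 0.09 and Ccn1 at 1.23 ± 0.09. Of 33 TGF-beta and BMP pathway genes 3 rose and 6 fell (3 and 6, adjusted p = 0.273).

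Single genes fell among 16 cartilage genes (1 over the list alone, adjusted p = 0.946), 16 skeletal muscle genes (1, adjusted p = 0.347) and 20 interferon response genes (1, adjusted p = 0.27). Of 11 housekeeping genes 1 rose (0, adjusted p = 0.685). In limma 0 of 19 osteoblast genes passed (1 at an unadjusted p under 0.05, camera adjusted p = 0.273). Nor did any of 37 cell cycle genes (0 in limma, 8 unadjusted, adjusted p = 0.546) or of 17 cholesterol synthesis genes (0, 1 unadjusted, adjusted p = 0.239). Of the markers of other cell types, 0 of 10 macrophage (0 unadjusted, adjusted p = 0.571) and 0 of 10 endothelial genes passed (2 unadjusted, adjusted p = 0.77). Among 10 epithelial markers 0 passed (2 unadjusted, 1 over the list alone, adjusted p = 0.946). Median, mean and test differed in sign for cyclin-dependent kinase inhibitors (-0.03, 0.01, down), circadian (-0.04, 0.03, up) and metallothionein genes (-0.05, 0.07, up). They also did so for TGF-beta (0.03, -0.06, down), endothelial (-0.0018, 0.0061, down) and epithelial genes (-0.02, -0.02, up).

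The 2-hour arrays were the noisier ones, with residual SDs of 0.332, 0.281, 0.183 and 0.435 in DMSO replicates 1 to 4 and of 0.209, 0.333, 0.168 and 0.209 in dex, against 0.108 to 0.205 for the 36-hour arrays. In simulated data with this noise 54.4 unchanged probes passed per run at 2 h, or 27.5% of calls. That share depends on the 200 probes changed per run and is not that of the measured calls. A fit of only the 2-hour arrays gave 294 genes instead of 625. Over the alternatives the adjusted p reached from 0.00417 to 0.198 for Cebpa, from 0.00246 to 0.152 for Il6, from 3.53e-04 to 0.108 for Lpl, and from 0.00119 to 0.115 for Per2. It reached from 0.0019 to 0.0625 for Fabp4, from 7.09e-04 to 0.0764 for Gata2, from 5.00e-04 to 0.0848 for Lcn2 and from 7.46e-04 to 0.0742 for Plin4.

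DMSO 2 h replicate 4 had a mean correlation of -0.104 across probes with the other arrays of its group. Without it the adipogenic transcription factors (camera adjusted p = 0.265, 0.00182 to 0.78 over the alternatives) and the receptor and steroid metabolism genes (adjusted p = 0.126, 0.00311 to 0.235) no longer passed at 2 h. The receptor and steroid list also ended without DMSO 2 h replicate 3 (adjusted p = 0.0701), and the Wnt pathway list without replicate 1 (adjusted p = 0.0635, 0.00258 to 0.103 over the alternatives). Mature adipocyte genes passed upward without DMSO 2 h replicate 4 (adjusted p = 0.0364) or dex 2 h replicate 2 (adjusted p = 0.048), with a range of 0.0364 to 0.244. Interferon response genes passed downward without DMSO 2 h replicate 4 (adjusted p = 0.0188, 3.22e-04 to 0.812 over the alternatives).

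The second comparison asked the same of 36 h. Mogat1, encoding a monoacylglycerol acyltransferase, was 18.3-fold higher with dex (log2 change 4.19 ± 0.14, SE, n = 4 per group, adjusted p = 5.73e-11). Glul was 14.3-fold higher, Fkbp5 8.62-fold (3.11 ± 0.12, adjusted p = 2.24e-10) and Fabp4 6.02-fold (2.59 ± 0.31, adjusted p = 5.87e-05). Pparg rose by 0.82 ± 0.15 on 1 of 3 probes (adjusted p = 0.00247), the others giving 0.61 and 0.29. The smooth muscle actin gene Acta2 was 3.85-fold lower (-1.95 ± 0.13, adjusted p = 1.22e-07) on the quoted probe, while its other 3 probes gave -0.72, -0.70 and -0.22, the last not passing (adjusted p = 0.101). The tropomyosin gene Tpm1 (-1.87 ± 0.09) and the matrix genes Tnc (-1.62 ± 0.08) and Postn (-1.45 ± 0.12) fell as well. The other probes gave -1.32 for Tpm1, -1.82 to -0.72 for Tnc and -1.52 for Postn. For each of these genes the 4 dex arrays lay on one side of the 4 DMSO arrays at 36 h. In DMSO between 2 and 36 h, Mogat1, Glul, Fkbp5 and Pparg fell by at least 1 probe. Acta2, Tpm1, Tnc and Postn rose there, and Fabp4 did not pass. Except for Fabp4, the changes with dex at 36 h are thus measured from a DMSO level that moved the other way.

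In all, 2300 genes changed at 36 h, 1326 upward, 948 downward and 26 in both directions on different probes. Of these, 268 did so by at least 1 on the log2 scale (206 up, 62 down). The largest rise was that of Zcchc14 (4.63 ± 0.13, adjusted p = 1.43e-11), whose other probe gave -0.09. Others were Plxdc1 (4.11 ± 0.14), the neurotrophic factor gene Artn (4.00 ± 0.23, other probes 0.17 and 0.11) and 1700018A23Rik (3.98 ± 0.15). They were followed by the adenylyl cyclase gene Adcy3 (3.84 ± 0.13, other probes 0.02 and 0.08), Mrnip (3.55 ± 0.20, other probe -0.04), Ncf4 (3.52 ± 0.25) and Thap8 (3.49 ± 0.22). The largest falls were those of A630052E07Rik (-2.40 ± 0.21), Sycp2 (-2.01 ± 0.25, other probe -0.94), C430049B03Rik (-1.98 ± 0.15) and 9430052C07Rik (-1.90 ± 0.18). The growth factor gene Ptn, encoding pleiotrophin, fell by 1.89 ± 0.18. Others were Col12a1 (-1.85 ± 0.10, other probe -0.14), Cxcl5 (-1.78 ± 0.23) and Sfrp2 (-1.67 ± 0.13), a secreted Wnt modulator. Of 1172 changed genes with several probes, 833 passed by 1 probe and 194 by all. The dex arrays were apart from the DMSO arrays for 10296 probes, or 26.8%, where chance gives 2.86%.

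**Figure D2:**
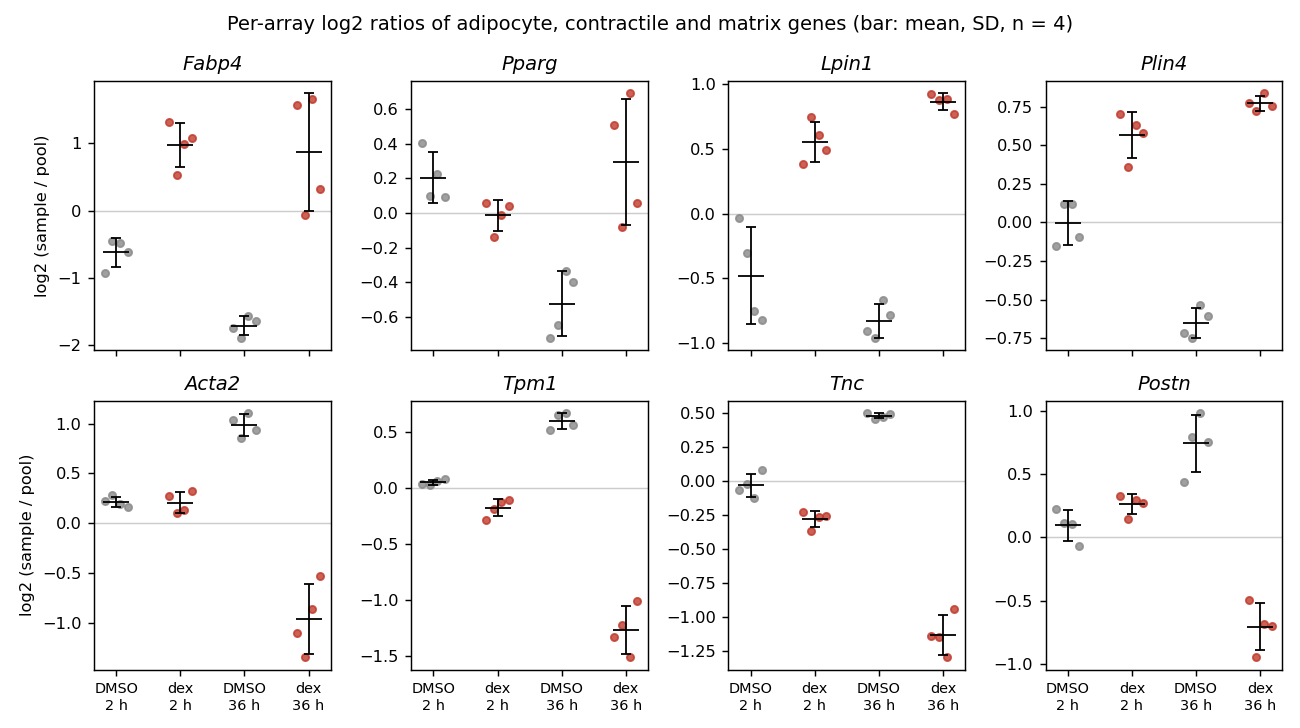
Log2 ratio of sample over pool (vertical axis) on each of the 16 arrays for 8 genes, 1 probe per gene, in the 4 groups, with bars for mean and SD (n = 4). At 36 h Fabp4, Pparg, Lpin1 and Plin4 were higher with dex, and Acta2, Tpm1, Tnc and Postn were lower.

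Of 32 mature adipocyte genes 11 rose and 0 fell at 36 h (12 and 0 over the list alone, camera adjusted p = 9.01e-05, adjusted p = 0.00664 with an estimated correlation). They included Lpin1 (1.69 ± 0.15, other probes 0.87 and 0.32), the angiotensinogen gene Agt (1.68 ± 0.24), Orm1 (1.64 ± 0.21) and the lipid droplet gene Plin4 (1.42 ± 0.09). Adipoq, encoding adiponectin, had a value of 0.19 ± 0.08 (adjusted p = 0.211). Of 29 adipogenic transcription factors 12 rose and 3 fell (12 and 5 over the list alone, camera adjusted p = 9.25e-04, adjusted p = 0.235 with an estimated correlation). Cebpb rose by 0.87 ± 0.10 and Cebpd by 0.87 ± 0.13. The glucocorticoid receptor target list had 28 rises and 0 falls among 39 genes (30 and 1 over the list alone, camera adjusted p = 4.32e-31, adjusted p = 6.53e-04 with an estimated correlation). Lcn2 rose by 3.19 ± 0.26. Of 12 receptor and steroid metabolism genes 5 rose and 0 fell (6 and 1, camera adjusted p = 0.0038, adjusted p = 0.138 with an estimated correlation). Among them was Hsd11b1, which regenerates active glucocorticoid (0.67 ± 0.16, on 1 of 2 probes). The 34 preadipocyte markers and inhibitors of adipogenesis had 4 rises and 12 falls (5 and 12, camera adjusted p = 0.00535, adjusted p = 0.138 with an estimated correlation). Among the falls were Id2 (-1.50 ± 0.14), Gata2 (-1.36 ± 0.16) and Dlk1 (-0.86 ± 0.17).

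Of the 19 contractile and actin cytoskeleton genes 10 fell and 0 rose (13 over the list alone, camera adjusted p = 1.76e-10, adjusted p = 6.53e-04 with an estimated correlation). Actb fell by 0.82 ± 0.10 on the quoted probe, with 24 of its 32 probes passing and the others at -0.60 to -0.23. Of 49 extracellular matrix genes 9 rose and 22 fell (13 and 25 over the list alone, camera adjusted p = 1.39e-04, adjusted p = 0.138 with an estimated correlation). The basement membrane collagen gene Col4a1 (1.60 ± 0.09) rose whereas the fibrillar collagen gene Col1a1 (-0.72 ± 0.10) fell. Of 19 osteoblast genes 0 rose and 3 fell (0 and 3, camera adjusted p = 0.0124, adjusted p = 0.0663 with an estimated correlation). The 3 were Col1a1, Col1a2 and Postn, matrix genes that fibroblasts also express. Of 37 cell cycle genes 12 rose and 1 fell (18 and 1, camera adjusted p = 8.75e-06, adjusted p = 0.281 with an estimated correlation). Nusap1 rose by 1.22 ± 0.18, the cyclin gene Ccnd1 by 0.94 ± 0.11 on 2 of 4 probes and Top2a by 0.72 ± 0.16. Of 20 cyclin-dependent kinase inhibitors and quiescence genes 8 rose and 1 fell (8 and 1, camera adjusted p = 6.77e-05, adjusted p = 0.0226 with an estimated correlation). Gas6, a ligand of receptor kinases, rose by 1.38 ± 0.10, and Gas2 fell by 1.10 ± 0.13, its other probe giving -0.09. The 21 metallothionein and antioxidant genes had 8 rises and 2 falls (9 and 2, camera adjusted p = 0.0015, adjusted p = 0.103 with an estimated correlation). Mt2 rose by 2.22 ± 0.11 and Mt1 by 1.65 ± 0.11. Of 20 interferon response genes 0 rose, 5 fell and 1 did both (0 and 8, camera adjusted p = 0.00448, adjusted p = 0.406 with an estimated correlation). Ifit1 fell by 0.86 ± 0.14.

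The remaining lists did not pass the camera test at 36 h. The 39 inflammatory and NF-kappaB target genes had 4 rises and 8 falls (7 and 11 over the list alone, adjusted p = 0.202). The matrix protease gene Mmp3 (-1.49 ± 0.15) and the adhesion gene Vcam1 (-1.20 ± 0.09) fell, and Il6 had a value of -0.01 ± 0.12. Of 36 immediate early genes 10 rose and 4 fell (11 and 7, adjusted p = 0.315). Myc rose by 1.80 ± 0.15 (other probe 0.68) and Egr1 fell by 1.63 ± 0.16. There were 5 rises and 10 falls, and 2 genes with both, among 33 TGF-beta and BMP pathway genes (6 and 10, adjusted p = 0.197). The same counts were 3, 3 and 1 among 29 Wnt pathway genes (4 and 7, adjusted p = 0.19). There were 5 rises and 4 falls among 26 insulin and IGF signalling genes (7 and 6, adjusted p = 0.645) and 3 and 2 among 19 circadian clock genes (6 and 2, adjusted p = 0.273). Of 17 cholesterol synthesis genes 2 rose (2, adjusted p = 0.144). Of 16 cartilage genes 1 rose and 2 fell (3 and 4, adjusted p = 0.801), among them Fmod (-1.03 ± 0.12). In limma 0 of 16 skeletal muscle genes passed, and 3 had an unadjusted p under 0.05 (adjusted p = 0.946). Of the markers of other cell types, the epithelial keratin gene Krt8 rose (1.15 ± 0.08, 1 of 10 epithelial markers, 1 over the list alone, adjusted p = 0.0628). The endothelial marker Flt1 rose (0.65 ± 0.16, 1 of 10, adjusted p = 0.9999) and the macrophage marker Lyz2 fell on 1 of 3 probes (-0.56 ± 0.09, 1 of 10, adjusted p = 0.486). Of 11 housekeeping genes 3 rose, 3 fell and 2 did both (4 and 3, adjusted p = 0.685). The called share of this list was 72.7%, against 71.8% for the glucocorticoid receptor targets. A gene counts by any 1 of its probes, so called shares are not directly comparable between lists whose genes differ in probe number. Median, mean and test differed in sign for cartilage (0.0041, -0.04, down), skeletal muscle (-0.02, 0.03, up) and immediate early genes (-2.4e-04, 0.05, up). So they did for endothelial (-0.0061, 0.04, up) and housekeeping genes (-0.0082, 0.06, down).

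**Figure D3:**
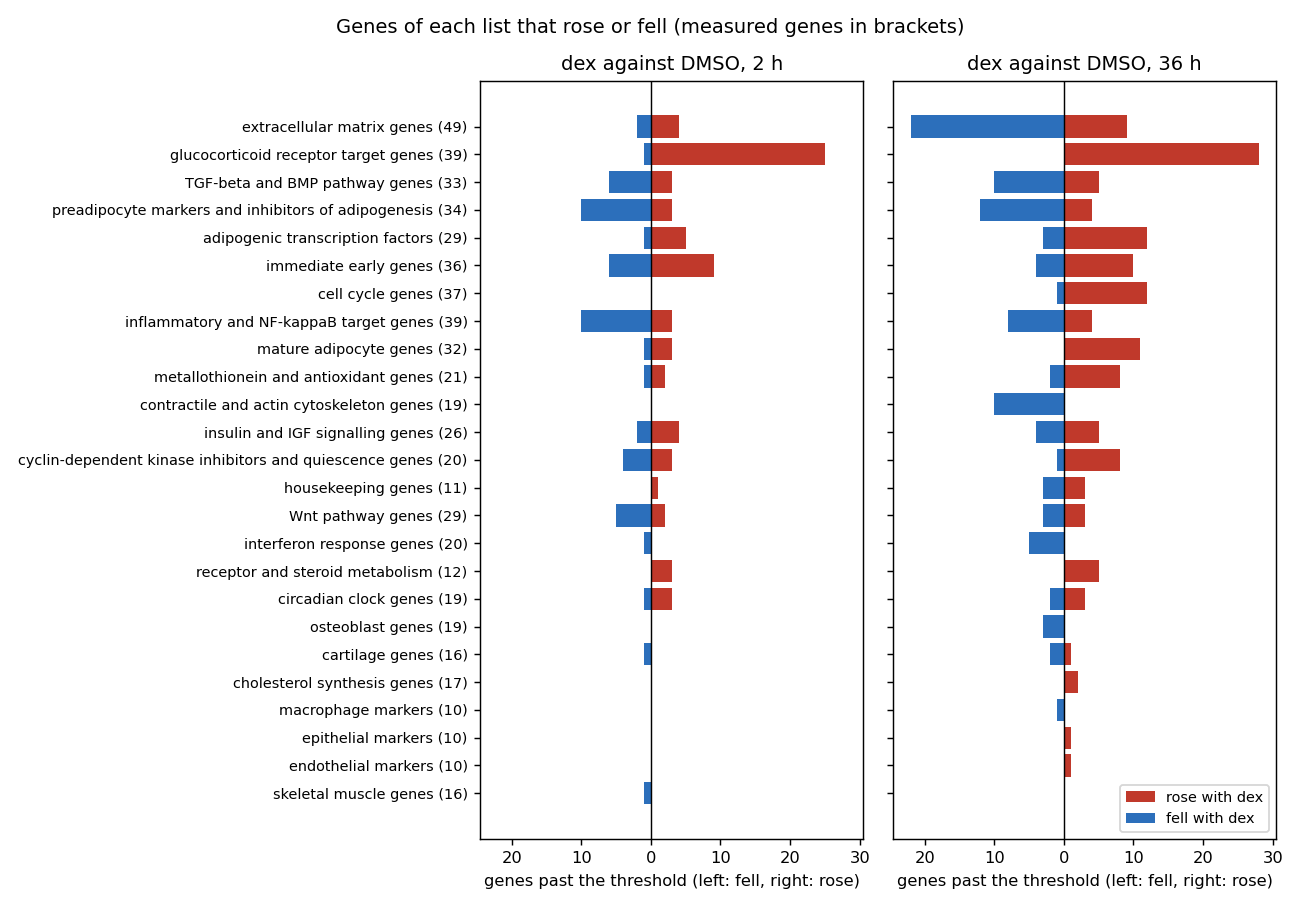
Number of genes of each of the 25 lists that rose or fell with dex at 2 and 36 h (horizontal axis, genes), by list (vertical axis). At 36 h 11 mature adipocyte genes rose and 0 fell, and 10 contractile genes fell and 0 rose.

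The number of genes at 36 h depended on the processing, with 1028 at the log-odds threshold and 4555 in a fit of the 36-hour arrays alone. The excess of rises, which made up 57.7% of the 2300, depended on it too. It was small with centred and scaled arrays (4175 genes, 2227 up, 1858 down) and with quantile normalization (4349 genes, 2174 up, 2075 down), and turned with array weights (9087 genes, 4235 up, 4325 down). Leaving out 1 array gave 1289 to 3082 genes, with 1289 without dex 36 h replicate 1 and 1364 without its replicate 3. It gave 1342, 1306 and 1490 without DMSO 36 h replicates 1, 2 and 4. Over the alternatives the adjusted p of Hsd11b1 ranged from 2.82e-05 to 0.0775 and that of Flt1 from 1.14e-04 to 0.0717. Without dex 36 h replicate 2 the interferon response genes no longer passed (camera adjusted p = 0.0509, 5.99e-04 to 0.406 over the alternatives). Cholesterol synthesis genes passed upward without dex 36 h replicate 2 (adjusted p = 0.0351) or 4 (adjusted p = 0.0235), with a range of 0.0235 to 0.741.

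Dex effects at both times were set against each other on separate vehicle arrays. Of 19640 genes, 222 rose at both times, where independent lists would share 26.1, and 82 fell at both, where they would share 11.5. Another 7 rose at 2 h and fell at 36 h (18.7 for independent lists), and 16 did the reverse (16.1). Across genes, which are not independent replicates, the effects had a Pearson r of 0.32 and a Spearman rho of 0.21. Of 613 genes called at 2 h by their quoted probe, 514 (83.8%) had the same sign at 36 h.

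**Figure D4:**
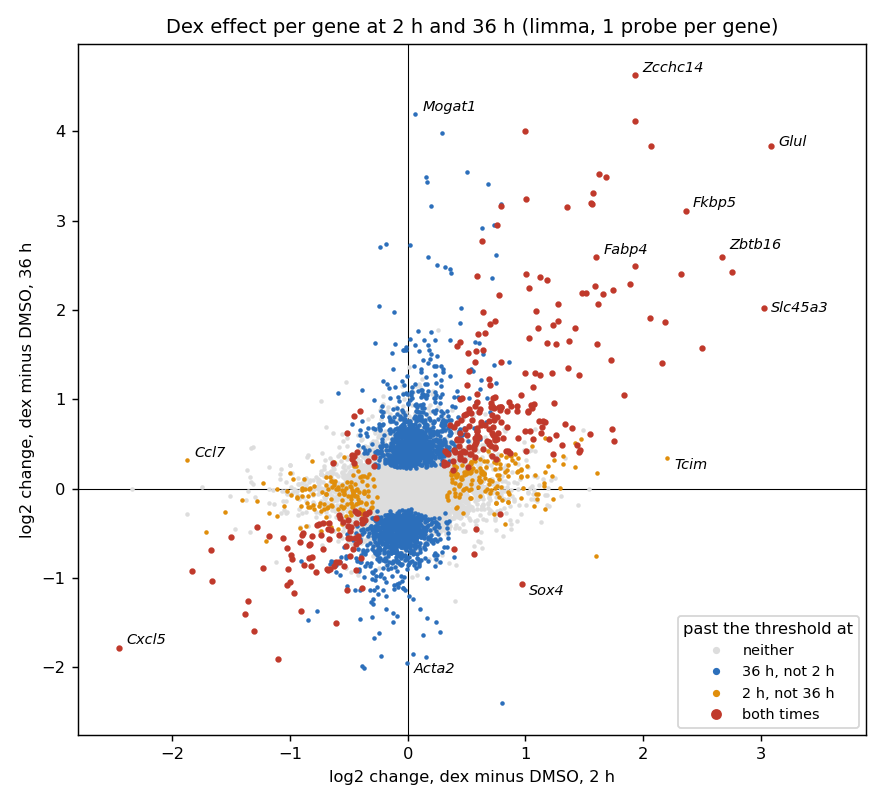
Log2 change with dex at 2 h (horizontal axis) against that at 36 h (vertical axis) for single genes, each by 1 probe, with named genes labelled. Zbtb16 had nearly the same change at both times, and Sox4 rose at 2 h and fell at 36 h.

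The test of the difference between times was passed by 683 genes, 416 with a more positive effect at 36 h and 267 with a more negative one. The count was 1405 (783 and 612) with quantile normalization, 1414 (832 and 571) with centred and scaled arrays and 1847 (1051 and 782) with array weights. Mogat1 differed by 4.13 ± 0.20 (adjusted p = 6.38e-08), as it was 0.06 ± 0.14 at 2 h. Other large differences were those of 1700018A23Rik (3.69 ± 0.21), Epb41l5 (3.34 ± 0.41) and Ear10 (3.27 ± 0.48). Then came Mrnip (3.04 ± 0.28), Artn (3.00 ± 0.33), Pacc1 (2.97 ± 0.27) and Hrh4 (2.93 ± 0.52). Other probes gave 0.09 for Epb41l5, -0.05 for Mrnip and -0.13 and 0.37 for Artn. The most negative were those of A630052E07Rik (-3.20 ± 0.30), Hectd2 (-2.35 ± 0.46), Ptn (-2.04 ± 0.25) and the transcription factor gene Sox4 (-2.04 ± 0.17). After these came Acta2 (-1.94 ± 0.19), Col12a1 (-1.90 ± 0.14), Serpinb3a (-1.87 ± 0.17) and Tcim (-1.86 ± 0.23). Other probes gave -0.66, -0.64 and -0.24 for Acta2, -0.26 for Col12a1 and -0.36 for Serpinb3a. Sox4 rose by 0.97 ± 0.12 at 2 h and fell by 1.07 ± 0.12 at 36 h, on both of its probes. The effect on Ccl7 was -1.87 ± 0.16 at 2 h and 0.32 ± 0.16 (adjusted p = 0.285) at 36 h, a difference of 2.19 ± 0.23, while in vehicle Ccl7 fell by 0.88 ± 0.16 between the times (adjusted p = 0.0157). For Zbtb16 (-0.07 ± 0.14, adjusted p = 0.858), Rhob (0.08 ± 0.12, adjusted p = 0.824) and Tsc22d3 (-0.33 ± 0.34, adjusted p = 0.716) no difference was detectable. Of 1972 genes called at 36 h and not at 2 h, 454 passed this test.

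By list, the effect at 36 h was higher for mature adipocyte genes (6 of 32 more positive, 0 more negative, 8 and 0 over the list alone, camera adjusted p = 0.00334, adjusted p = 0.0284 with an estimated correlation). It was lower for contractile genes (0 and 4 of 19, 0 and 9, adjusted p = 4.10e-05, adjusted p = 0.0284 with an estimated correlation). Extracellular matrix genes had 4 more positive and 14 more negative effects among 49 (7 and 23, adjusted p = 1.97e-05, adjusted p = 0.0796 with an estimated correlation). The effect was also higher for cyclin-dependent kinase inhibitors and quiescence genes (7 and 2 of 20, 8 and 2, adjusted p = 2.92e-04, adjusted p = 0.0284 with an estimated correlation). For osteoblast genes it was lower (0 and 2 of 19, 0 and 3, adjusted p = 0.00297, adjusted p = 0.0284 with an estimated correlation). The epithelial markers, a list of another cell type, also had a higher effect at 36 h (1 and 0 of 10, 1 and 0 over the list alone, adjusted p = 0.0385, adjusted p = 0.114 with an estimated correlation), and the gene that passed was Krt8. The effect was higher too for cell cycle genes (2 and 0 of 37, 5 and 0, adjusted p = 5.85e-04, adjusted p = 0.467 with an estimated correlation) and for metallothionein and antioxidant genes (4 and 1 of 21, 9 and 2, adjusted p = 5.87e-04, adjusted p = 0.0668 with an estimated correlation). Of 17 cholesterol synthesis genes 0 passed in limma and 4 had an unadjusted p under 0.05, and the list was higher (1 over the list alone, adjusted p = 0.0229, adjusted p = 0.531 with an estimated correlation). These were the 9 of 25 lists that passed for this difference, 4 of them with an estimated correlation. Those 4 also passed in vehicle over time, in the opposite direction, and the DMSO arrays enter both comparisons. For Fkbp5, whose difference was 0.74 ± 0.17, the adjusted p ranged from 0.0201 to 0.275 over the alternatives. For Ccl2 (0.92 ± 0.20) it ranged from 2.17e-04 to 0.462 and for Pparg (1.03 ± 0.21, other probes 0.28 and -4.4e-04) from 0.00252 to 0.174.

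Without the 3 most variable 2-hour arrays, left out after the data were seen, the difference no longer passed for mature adipocyte genes (adjusted p = 0.0667, 0.0019 to 0.0667 over the alternatives) and osteoblast genes (adjusted p = 0.0581, 0.00157 to 0.0581). It also ended for cholesterol synthesis genes (adjusted p = 0.0667, 0.00322 to 0.531) and epithelial markers (adjusted p = 0.0807, 0.0231 to 0.114). The epithelial list further ended without DMSO 2 h replicates 1 (adjusted p = 0.108) or 3 (adjusted p = 0.0556), dex 2 h replicate 1 (adjusted p = 0.114) or DMSO 36 h replicate 2 (adjusted p = 0.0503). The cholesterol list did so without DMSO 2 h replicate 1 (adjusted p = 0.271), dex 2 h replicate 1 (adjusted p = 0.0632) or dex 36 h replicate 1 (adjusted p = 0.0636). Interferon response genes (0 of 20 in limma, 6 at an unadjusted p under 0.05, adjusted p = 0.0722 on all arrays) passed with a lower effect at 36 h in 6 of the 16 fits without 1 array. These were the fits without DMSO 2 h replicates 2 (adjusted p = 0.018) or 3 (adjusted p = 0.0454), dex 2 h replicates 3 (adjusted p = 0.0399) or 4 (adjusted p = 0.0239) and dex 36 h replicates 1 (adjusted p = 0.0352) or 3 (adjusted p = 0.0261), with a range of 0.018 to 0.957 over the alternatives. Inflammatory genes (adjusted p = 0.107 on all arrays) passed with a higher effect without dex 36 h replicate 2 (adjusted p = 0.0396, 0.0396 to 0.472 over the alternatives).

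In vehicle alone, which received the solvent for either time, 53 genes rose and 195 fell from 2 to 36 h. Mogat1 fell by 3.43 ± 0.14 (SE, n = 4 per group, adjusted p = 5.92e-09), although it was higher with dex at 36 h. Other falls were those of Artn by 2.74 ± 0.23, 1700018A23Rik by 2.72 ± 0.15, Epb41l5 by 2.67 ± 0.29, Hrh4 by 2.59 ± 0.37 and Zcchc14 by 2.32 ± 0.13. Other probes gave -0.10 and -0.20 for Artn, 0.0064 for Epb41l5 and -0.20 for Zcchc14. Rises were those of Fam221b (2.13 ± 0.44), Ptn (1.34 ± 0.18), Tcim (1.01 ± 0.16), the long non-coding RNA gene Malat1 (0.89 ± 0.16), Adam21 (0.83 ± 0.17) and Actb (0.82 ± 0.10). The other probe of Malat1 gave 0.37 (adjusted p = 0.328), and the other probes of Actb gave 0.10 to 0.61, of which 3 passed. Of 19 contractile genes 3 rose and 0 fell, and the list moved up (6 and 0 over the list alone, camera adjusted p = 3.82e-04, adjusted p = 0.0284 with an estimated correlation). Of 32 mature adipocyte genes 4 fell and 0 rose, and the list moved down (8 and 0 over the list alone, adjusted p = 0.00431, adjusted p = 0.0304 with an estimated correlation). Among 39 glucocorticoid receptor targets 4 fell and 0 rose (10 and 1, adjusted p = 0.00334, adjusted p = 0.347 with an estimated correlation). In vehicle 12 of the 25 lists passed, and 4 did so with an estimated correlation. Besides the contractile and mature adipocyte lists, these 4 held osteoblast genes (2 rises, 0 falls, 6 and 0, adjusted p = 0.00148, adjusted p = 0.0284 with an estimated correlation). The fourth list was cyclin-dependent kinase inhibitors and quiescence genes (0 rises, 3 falls, 2 and 9, adjusted p = 1.77e-04, adjusted p = 0.0284 with an estimated correlation). The same 4 lists passed with an estimated correlation for the difference between times, each in the opposite direction. That difference includes the vehicle change on the same DMSO arrays with its sign turned, so these results are not independent.

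Of the 206 genes that rose by at least 1 (log2) with dex at 36 h, 105 were among the 195 that fell in vehicle, against 2.05 for independent lists. Both comparisons used the 4 DMSO 36 h arrays. Ranked by limma's moderated t, a measure chosen after the data were seen, the top 206 rises with dex and the top 195 falls in vehicle shared 117 genes. In 10 simulated runs of unchanged groups lists of these lengths shared 9 to 24, with a median of 15.5. With those arrays split so that none entered both comparisons, between 183 and 213 genes rose by as much over 6 splits, and 90.9% to 96.2% of them had a negative change in vehicle, with medians between -0.72 and -0.54. Between 45 and 66 of them fell by the test.

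Time and array batch cannot be told apart here, since the labels give no batch. The count of 248 genes, 21.4% of them rises, was 531 without DMSO 2 h replicate 4 and 120, 128, 140 and 120 without DMSO 36 h replicates 1, 2, 3 and 4, and 750 with quantile normalization (39.2% rises). The mature adipocyte list no longer passed in vehicle without DMSO 2 h replicate 4 (camera adjusted p = 0.0937, 0.0019 to 0.0937 over the alternatives). Without the 3 most variable 2-hour arrays the osteoblast list (adjusted p = 0.0667, 6.44e-04 to 0.0667) and the glucocorticoid receptor target list (adjusted p = 0.0667, 2.39e-04 to 0.347) did not pass either. The other 7 lists that passed in vehicle, which were extracellular matrix genes upward and adipogenic transcription factors, cell cycle, circadian clock, immediate early, cholesterol synthesis and metallothionein genes downward, did not pass with an estimated correlation (adjusted p between 0.0606 and 0.531). Without DMSO 2 h replicate 1 the adipogenic, cell cycle, circadian, immediate early and cholesterol lists ended (adjusted p between 0.107 and 0.307), and the first 4 of these ended without replicate 2 (adjusted p between 0.111 and 0.139). The immediate early list also ended without DMSO 2 h replicate 3 (adjusted p = 0.0952), the matrix list without replicate 4 (adjusted p = 0.125) and the circadian list without DMSO 36 h replicate 2 (adjusted p = 0.0527). Receptor and steroid metabolism genes passed downward in vehicle without DMSO 2 h replicate 3 (adjusted p = 0.0386) or DMSO 36 h replicate 3 (adjusted p = 0.038), with a range of 0.038 to 0.467. Interferon response genes did so without the 3 most variable 2-hour arrays (adjusted p = 0.0475, 0.0475 to 0.938 over the alternatives).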

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

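The tests of single-probe signal, of 2-hour noise and of treatment length described here were chosen only after the result was seen. The others were set down before their own results were seen, but not all of them before the data were seen. Those on genes that rose with dex and fell in vehicle concern a pattern found in these data. Leaving out the most variable 2-hour arrays was likewise chosen after the data were seen.

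Of 404 groups of 4 arrays, for the 98 genes described and for the median, residual SD and replicate correlation of the arrays, 26 (6.44%) had 1 array far from the other 3, its gap to the nearest exceeding the 95% critical value of Dixon's test for the group's range; chance marks about 1 in 20 groups. Over all 231 genes of the naming rule, 67 of 924 groups (7.25%) did. The arrays with the most were dex 2 h replicate 2, with 5 of the 26, and DMSO 2 h replicate 1, with 4. The values are log2 ratios of sample over pool. In DMSO 2 h, replicate 1 stood apart for Angptl4 (0.85), C430049B03Rik (0.31), Sfrp2 (0.49) and Tsc22d3 (-0.97), replicate 2 for Sycp2 (0.46), replicate 3 for Mmp3 (-0.38) and replicate 4 for 9430052C07Rik (0.19), Hectd2 (-2.41) and Hrh4 (0.47). In dex 2 h, replicate 2 stood apart for Gadd45g (1.37), Hectd2 (1.06), Hrh4 (-1.02), Mt2 (0.61) and Nusap1 (0.63), replicate 1 for Angptl4 (-0.76) and replicate 4 for Gas6 (0.32). In DMSO 36 h these were Nusap1 in replicate 3 (-0.26) and Fmod in replicate 4 (0.43). In dex 36 h, replicate 2 stood apart for Angptl4 (-0.60), Plk2 (-0.75) and Tsc22d3 (1.30), replicate 3 for C430049B03Rik (-1.998), Fam221b (1.14) and Per1 (-0.17), and replicate 4 for Pacc1 (0.22) and Sfrp2 (-0.79).

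The differences below are those of the quoted probe, and for Klf5 the mean over its probes had the opposite sign. Of all 19640 genes, 683 passed limma's test of the difference between times. The naming rule took the largest such differences, so a higher share of the 98 genes was built in. For 60 of the 98 the dex effect differed by this test, given as the log2 effect at 36 h minus that at 2 h. It was more positive at 36 h for Mogat1 (4.13), 1700018A23Rik (3.69), Epb41l5 (3.34), Ear10 (3.27), Mrnip (3.04), Artn (3.00), Pacc1 (2.97), Hrh4 (2.93), Zcchc14 (2.69), Ccl7 (2.19), Plxdc1 (2.18), Ncf4 (1.89), Thap8 (1.81), Adcy3 (1.77), Agt (1.66), Lcn2 (1.62), Cxxc5 (1.29), Slc40a1 (1.29), Angptl4 (1.24), Col4a1 (1.18), Gas6 (1.09), Pparg (1.03), Plk2 (0.99), Socs5 (0.97), Ccl2 (0.92), Ccnd1 (0.87), Krt8 (0.87), Plin4 (0.85), Klf3 (0.82), Lpl (0.81) and Fkbp5 (0.74). It was more negative for A630052E07Rik (-3.20), Hectd2 (-2.35), Ptn (-2.04), Sox4 (-2.04), Acta2 (-1.94), Col12a1 (-1.90), Serpinb3a (-1.87), Tcim (-1.86), Egr1 (-1.77), Adam21 (-1.74), Tpm1 (-1.64), Sycp2 (-1.64), Postn (-1.62), C430049B03Rik (-1.59), Sfrp2 (-1.39), Tnc (-1.37), Mmp3 (-1.37), Gadd45g (-1.22), Vcam1 (-1.21), Adamts1 (-1.18), Klf5 (-1.04), Fmod (-0.98), Malat1 (-0.98), Foxo3 (-0.96), Actb (-0.92), Id2 (-0.89), Gas2 (-0.84), Col1a1 (-0.77) and Lyz2 (-0.60).

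Of the 9011 probes that name no single gene, which entered no count of genes, 69 passed for dex at 2 h, 588 for dex at 36 h, 108 for the difference between times and 45 for vehicle over time.

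Of the 35 splits of the 8 arrays of dex and DMSO at 2 h into 4 and 4, 1 gave as many as 625 genes, the real one, and the highest other gave 38. At 36 h 1 of 35 did, with 2300 genes against 0 as the highest other, and for vehicle over time 1 of 35, with 248 against 0. For the difference between times 1 of 100 drawn regroupings, the real one, gave as many as 683, and the highest other gave 36. No other grouping tried gave as many genes, though 1 of 35 is the smallest share these splits allow. Regroupings that mix groups carry real differences into the spread, which lowers their counts. They do not tell how many called genes are unchanged. In simulated data with 200 changed probes, 27.5% of calls at 2 h were unchanged probes. That share depends on the number changed. In the measured data 855 probes passed at 2 h, so the share does not carry over to them.

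By their quoted probe, 102 genes rose by at least 1 (log2) with dex at 36 h and fell in vehicle over time, with a median dex effect of 1.67 at 36 h and 0.28 at 2 h. One transcript shared by most of these probes is argued against. The median correlation of the probes' deviations from group means was 0.106, above that of only 2.3% of random sets. Those were 1000 sets of 50 probes drawn from the 94 other risers. A median over all pairs cannot show a transcript shared by only some of the probes. Noise of the 3 most variable 2-hour arrays is argued against too, as the median fall without them was 105% of that with them (-0.94 against -0.90). Signal of single probes stays open: other probes stayed near 0 for 27 of 41 such genes with several probes (65.9%) and for 21 of 38 other risers (55.3%; Fisher's exact test, two-sided, p = 0.365). A loss of expression in vehicle that dex counteracted may be a biological explanation. For these genes it cannot be told apart from single-probe signal or a batch of the DMSO 36 h arrays alone. A batch that followed time alone would shift dex and DMSO at 36 h alike. It could give the fall in vehicle but no dex effect at 36 h. These genes were picked by a dex effect of at least 1 (log2) at 36 h, so their median of 1.67 does not test this.

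More genes changed at 36 h than at 2 h. Noise that is independent between arrays does not change the expected covariance of the dex effect between separate pairs of replicates. That covariance was at least 0.0660 at 36 h and between -0.0183 and 0.0301 at 2 h. Greater independent noise of the 2-hour arrays is thus argued against as the whole cause. Opposed deviations of 2-hour replicates could lower the covariance at 2 h. In DMSO 2 h the lowest correlation between replicates was -0.256, so noise of that kind stays open. A longer treatment reaching more genes could give the larger covariance at 36 h, but the ratio of the medians, 4.81, is not a stable multiple because the values at 2 h span 0. However, probes of olfactory and vomeronasal receptor genes, which should be silent here, had 49.8% of the covariance of other named probes at 36 h (46.9 to 51.9% over the pairings). Deviations shared by replicate arrays may therefore add to the count at 36 h, and they cannot be told apart from a longer treatment, since the limit set beforehand lay inside that range.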

How the results depend on the processing

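The fit without the 3 most variable 2-hour arrays and that of probes with a listed gene were chosen only after the data were seen. Of 537 pairs of a gene and a comparison, 297 passed, 213 of them under each alternative but the minimum change of 1 (log2), and 2 reversed, both with the mean over a gene's probes: Sdha for dex at 36 h (-0.22) and Klf5 for the difference between times (0.095), as their probes disagree. Counts of genes are given for those that moved by over 1.5 times. Quantile normalization gave 4349 at 36 h, 1405 for the difference between times and 750 in vehicle, and centring with scaling 4175, 1414 and 680. The log-odds threshold gave 1028 at 36 h and 40 genes down at both times. A minimum change of 1 (log2), which only removes genes, left 136 at 2 h, 268 at 36 h, 193 for the difference and 51 in vehicle. A fit of only the groups compared gave 294 at 2 h, 4555 at 36 h and 94 in vehicle, and array weights 9087 at 36 h, 1847 for the difference and 501 in vehicle. Without the 3 most variable 2-hour arrays there were 4709 at 36 h, 426 in vehicle and 130 down at both times. Lists passing camera fell from 7 to 1 at 2 h and from 12 to 4 at 36 h with an estimated correlation. Leaving out 1 array gave 475 to 781 genes at 2 h, 1289 to 3082 at 36 h, 456 to 911 for the difference, 120 to 531 in vehicle, and 6 to 8 and 12 to 13 lists at 2 and 36 h, though not always the same lists. At 36 h the count moved by over 1.5 times without dex 36 h replicates 1 (1289) and 3 (1364) and DMSO 36 h replicates 1 (1342), 2 (1306) and 4 (1490). In vehicle it did so without DMSO 2 h replicate 4 (531) and DMSO 36 h replicates 1 (120), 2 (128), 3 (140) and 4 (120). With the replicate number as a block (replicate block) the counts were 564 at 2 h, 1986 at 36 h, 533 for the difference and 176 in vehicle, and every change stayed under 1.5 times. Deviations of same-numbered arrays were correlated above 0.1 in 4 of 8 pairs (r = -0.10, 0.19, 0.04 and 0.26 at 2 h and -0.02, 0.34, 0.22 and -0.08 at 36 h). In 3 of 8 the same-numbered array was the best partner, so that not every pair deviated together and the numbers were not taken to pair the samples. Except for the 2 reversals and the minimum change, the cause was not tested. Signal over background is not known, so weak probes were neither removed nor bounded.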

Other observations

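Gene families were formed from shared symbol stems after the data were seen and fell outside the naming rule, and 225 families in 900 tests were searched for an excess of genes that changed one way. Fisher's exact test takes the genes of a family as independent, so its p values are too small where members vary together across arrays. Some clustered protocadherins, cell adhesion genes best known in neurons, fell with dex at 36 h. Of 22 members of the beta cluster 10 fell, where 1.06 would by chance (Fisher's exact test, adjusted p = 2.24e-05), with Pcdhb16 at -0.56 ± 0.08 (SE, n = 4 per group) and Pcdhb8 at -0.32 ± 0.08. Of 10 gamma A members 6 fell, where 0.483 would (adjusted p = 9.96e-04), among them Pcdhga7 (-0.57 ± 0.10) and Pcdhga8 (-0.70 ± 0.17). Over all members the median was -0.38 for the beta and -0.45 for the gamma A cluster, and it stayed negative with centred arrays (-0.37 and -0.45), quantile normalization (-0.45 and -0.55) and centring with scaling (-0.40 and -0.48). At 2 h the medians were 0.08 and -0.03. Members of a cluster are similar in sequence, and how far a probe reads its neighbours was not tested.

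Collagen genes went both ways at 36 h. Of 41, 9 fell, where 1.98 would by chance (adjusted p = 0.0356), and 6 rose, where 2.77 would (adjusted p = 0.847). Their median was -0.0032 and 21 of the 41 were lower, so no direction is given for the family as a whole. The median was 1.17e-04 with centred arrays, where centring moves all genes by nearly the same amount. It was -0.05 with quantile normalization and -0.04 with centring and scaling.

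Of 973 olfactory and vomeronasal receptor genes, whose expression is best known from sensory neurons, 1 passed with dex at 2 h (0.103%, against 3.34% of other genes) and 29 at 36 h (2.98% against 12.2%). For the difference between times 5 passed (0.514% against 3.63%), and in vehicle 2 (0.206% against 1.32%). A gene counts by any 1 of its probes. These 973 genes had 1012 probes, and all 19640 genes had 29456. With fewer probes per gene, their shares are not directly comparable with those of other genes.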
